A study of Toxicodendron succedaneum with 24 samples.

How the data were processed

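Total RNA from stem segments of Toxicodendron succedaneum was sequenced in 24 libraries, per the labels: sterile seedlings and explants as 2 sources, 4 times in rooting medium (6, 12, 24 and 48 h) and 3 replicates each. The extraction note also speaks of a time point before culture, which is not analysed here. The labels do not say whether replicates came from separate plants or cultures, so p-values measure the spread between these samples, which may be technical.

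The deposited table lists 54523 unigenes with an estimated count and an FPKM value (fragments scaled to unigene length and library size) for each library. The authors' counts are whole numbers, but 170 of 1308552 cells hold a count of 0 beside an FPKM above 0, so the counts were handled like estimated counts, also called expected counts, that had been cut to whole numbers before they were deposited. The deposited FPKM values were used as given, and 0 cells had an FPKM of 0 with a count above 0. The assembler, aligner and counting tool are not given in the sources used here. The table pairs no unigene with a gene name or description and no reference was used, so the gene lists and tissue marker lists fixed before the data were examined were not tested. How reads shared by near-identical unigenes were divided is not given either, so a level of a single unigene may include or lack reads of a close copy.

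Unigenes with an FPKM of at least 1 in at least 3 of the 24 libraries were tested, 31908 in all (58.5%). They held 96.79% of the reads of seedling 24 h replicate 3 and at least 99.1% in every other library. Library totals ranged from 13774616 to 19999098 reads, and 1 read in the smallest library corresponds to 0.0726 CPM. Limits for unigenes with 0 reads use 3 counts over the group and cover counting error only.

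The design fixed before the data were examined assumed FPKM values and limma. Because the table held counts, the main test was the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, trended dispersions, glmQLFit and glmQLFTest) in R 4.3.3, in 1 fit of 8 group means over all 24 libraries with 16 residual degrees of freedom; limma 3.58.1 on log2(FPKM + 1) was kept as an alternative. A unigene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested unigenes and an absolute log2 fold change of at least 1, two-sided. There were 12 contrasts (explant minus seedling, averaged and at each time; each later time minus 6 h within a source; the difference between sources of the change from 6 h to 48 h) and an F test over the interaction of source with time, which has no fold minimum. Expected overlaps are the product of the sizes of both lists divided by the number of tested unigenes, per direction. Lists from 1 fit share each unigene's dispersion and abundance, so they are not independent. An overlap above the expected value is therefore no test of a shared change. Principal components were taken from log2 CPM of the tested unigenes. Figures were drawn with matplotlib.

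Unigenes were named by a rule fixed before the data were examined: for each source contrast, the averaged contrast and the change from 6 h to 48 h in each source, at most 2 higher and 2 lower, those with the largest fitted log2 fold change among called unigenes whose libraries did not overlap between the groups (for the averaged contrast, at all 4 times). CPM values are TMM-scaled. A fold against a group with 0 reads is given as a lower bound. A few further unigenes are named in the closing part, chosen after their values were seen.

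The pipeline was tested on simulated counts drawn from the real means and library sizes for 31908 unigenes with 200 changed. The changed unigenes were drawn from those above a minimum expected count. With so few changed, the adjusted threshold is stricter than in comparisons with many calls, so these rates do not carry over directly. For the source difference at 6 h, 49% of changes of 1.5 and 78% of changes of 3 on the log2 scale were recovered, with 2 false calls. For explant 48 h against 6 h the values were 56% and 76% with 4 false calls, and for the averaged source difference 88% and 98% with 2.

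Replicates were compared before averaging: the lowest chi-square per unigene between libraries of a group was 16.1, where sampling noise alone gives about 1, so no library duplicated another of its group; pairs across groups were not compared. Alternatives were no filter, a mean FPKM of at least 5, median-ratio size factors, a pseudocount of 0.1, quantile normalization, limma without a trend, the replicate number as a block, fits of only the groups compared, and each replicate of the groups compared left out in turn. Leaving out 1 library also lowers the number of libraries in its group, which by itself can remove calls. Bounds on folds were also recomputed, after seeing the data, without each library of the higher group at unchanged scaling. After seeing the data, limma as first designed, DESeq2 1.42.0 and a fit without the 3 libraries that stood apart (seedling 24 h replicate 3, seedling 48 h replicate 3 and explant 12 h replicate 1) were added.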

Results

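RNA was sequenced from stem segments of Toxicodendron succedaneum, the wax tree, held on rooting medium and sampled after 6, 12, 24 or 48 h. The segments came from 2 sources, named in the labels as sterile seedlings and as explants, and each of the 8 combinations of source and time had 3 libraries, 24 in all. The stated aim of the series was to compare adventitious root development, the formation of roots from stem tissue, in stems that root with differing ability; the labels do not say which source rooted more readily. The file gave reads for 54523 unigenes, assembled transcript sequences without gene names, so single unigenes are named by their identifiers and grouped by how they changed. Libraries held 13774616 to 19999098 assigned reads, and 31908 unigenes were abundant enough to test.

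Time and source were the main axes of difference between libraries. The first principal component carried 24% of the variance and followed time: seedling libraries moved from a mean of -32.2 ± 8.4 (SD, n = 3) at 6 h to 56.9 ± 6.7 at 48 h, and explant libraries from -76.9 ± 8.1 to 50.8 ± 9.6. The second component, with 18.2%, separated the sources at every time, from -57.5 ± 3.8 against 14.3 ± 7.8 at 6 h to -21.2 ± 3.5 against 62.2 ± 3.1 at 48 h. The 12 h explant libraries were the most scattered (-60.4 ± 44.6 on the first component), because replicate 1 lay at -111.8 and the other 2 at -33.9 and -35.3. In that library the 100 most abundant unigenes took 21.2% of the reads, and in seedling 24 h replicate 2 they took 20.6%.

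**Figure D1:**
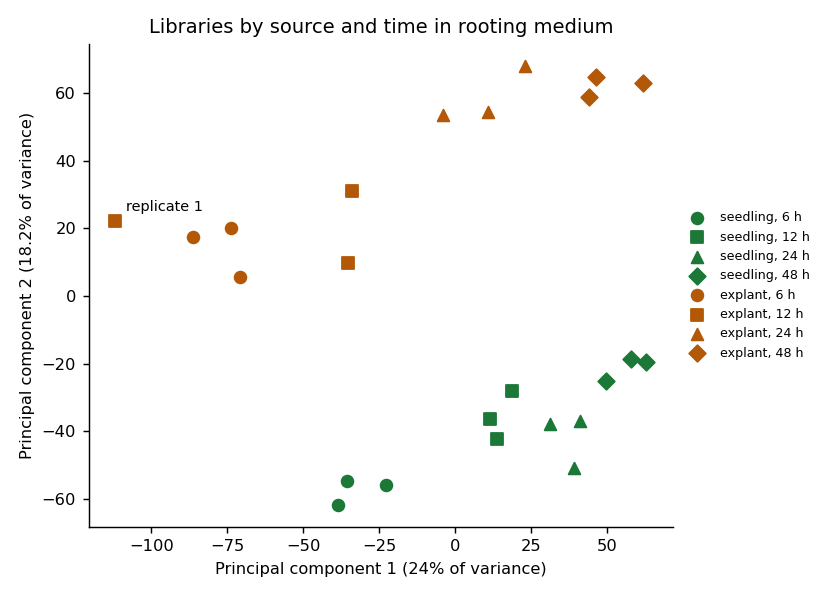
Each point is 1 library, placed by its scores on the first (24% of variance, x axis) and second (18.2%, y axis) principal components of log2 CPM; colour gives the source and shape the time in rooting medium. Libraries move to the right with time, the sources are separated vertically, and explant 12 h replicate 1 lies at -111.8 on the first component.

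Seedling libraries at 24 h and 48 h each included 1 library with reads on many more unigenes. Replicate 3 at 24 h had reads on 41156 unigenes and replicate 3 at 48 h on 40950, against 26520 to 32874 in the other 22 libraries. Most of the additional unigenes were not tested, since they did not reach an FPKM of 1 in 3 libraries; untested unigenes held 3.21% of the reads in the first of these libraries and 0.895% in the second.

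**Figure D2:**
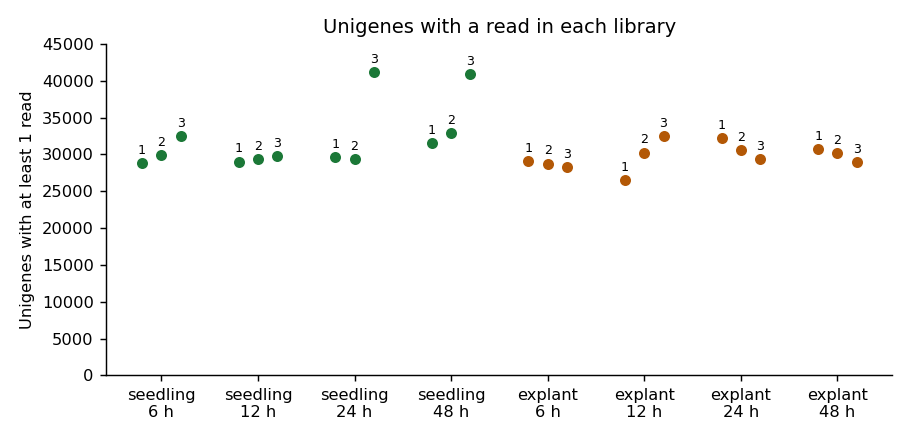
Points give the number of unigenes with at least 1 read (y axis) in each library, by group (x axis), with the replicate number above each point. Seedling 24 h replicate 3 (41156) and seedling 48 h replicate 3 (40950) lie above the other 22 libraries (26520 to 32874).

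The first question was how stems of the 2 sources differed whatever the time. Averaged over the 4 times, 3179 unigenes differed, 1541 higher and 1638 lower in explant stems, and 1289 of them differed by more than 4-fold. The clearest case was BMK_Unigene_106745, which had 0 reads in all 12 explant libraries and 2469 in the seedling libraries, at least 758-fold lower in explants against a floor of 3 counts over the group (edgeR quasi-likelihood, adjusted p = 1e-06). Its level in seedlings was 11.1 ± 9.2 CPM (counts scaled to library size; SD, n = 3) at 6 h, 15.3 ± 6.28 at 12 h, 6.76 ± 4.18 at 24 h and 13.6 ± 10.3 at 48 h. BMK_Unigene_118172 had 1679 reads in seedlings and 9 in explants, all 9 at 24 h, a 197-fold lower mean (adjusted p = 1.9e-06).

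In the other direction, BMK_Unigene_123341 averaged 21.8 CPM in explants and 0.778 in seedlings, a 28.1-fold ratio (adjusted p = 2e-05). It reached 30.7 ± 10.8 CPM (SD, n = 3) in explants at 24 h. Its seedling mean, and so the ratio, rests mostly on seedling 12 h replicate 1 (4.91 CPM) and seedling 48 h replicate 1 (3.32 CPM). BMK_Unigene_033666 averaged 8.4 CPM in explants and 0.679 in seedlings, a 12.4-fold ratio (adjusted p = 2.1e-05). All 4 unigenes were chosen from called ones whose libraries did not overlap between the sources at any of the 4 times. That trait is therefore no added support for them. In all, 500 of the 3179 called unigenes had it (161 higher and 339 lower in explants). At a single time chance gives no overlap in 10% of unigenes, in either direction. That share does not apply to the 500, which were already called and kept 1 direction at all 4 times. The count of 3179 fell to 1516 with limma on log2(FPKM + 1) and to 1024 when only unigenes with a mean FPKM of at least 5 were tested. With limma on log2(FPKM + 0.1) it was 3246, so the lower limma count went with the pseudocount of 1.

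**Figure D3:**
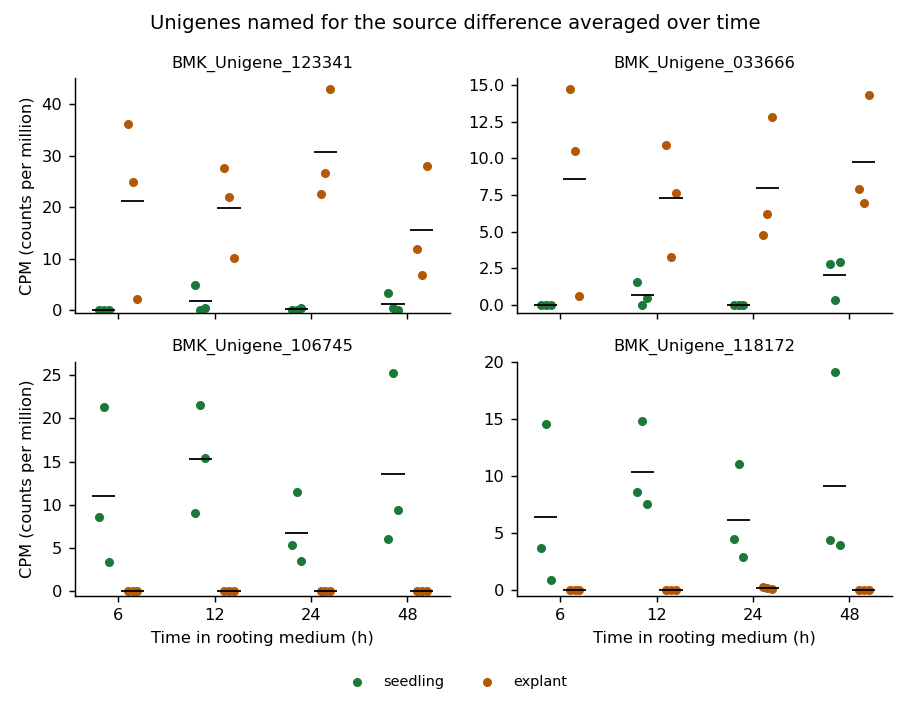
CPM (y axes, linear) in each library of the 4 unigenes named for the averaged source difference, by time in rooting medium (x axes), with green points for seedlings, orange points for explants and black lines for the mean of 3 libraries. BMK_Unigene_106745 is at 0 in all 12 explant libraries, and BMK_Unigene_123341 averages 21.8 CPM in explants against 0.778 in seedlings.

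At 6 h, 1277 unigenes differed between the sources, 735 higher and 542 lower in explants. BMK_Unigene_021862 had 0 reads in seedlings and 34.7 ± 12.2 CPM (SD, n = 3) in explants, at least 560-fold higher (adjusted p = 0.0086). BMK_Unigene_006255 also had 0 reads in seedlings and averaged 110 CPM in explants, but its explant libraries ranged from 0.344 to 296 CPM. Its adjusted p was 0.022; the call was lost with limma on log2(FPKM + 1), though not with a pseudocount of 0.1 (adjusted p = 0.033), and without any 1 of seedling replicates 1, 2 and 3 and explant replicate 1, with a largest adjusted p of 0.098. BMK_Unigene_106745 (11.1 ± 9.2 CPM) and BMK_Unigene_118172 (6.39 ± 7.22 CPM) were present in seedlings alone, at least 180-fold and at least 104-fold lower in explants (adjusted p = 0.0018 and 0.0036). Without seedling replicate 2, their highest library, these bounds fall to 96.9-fold and 37.3-fold. The count was 574 without seedling replicate 2, 753 without seedling replicate 3, 652 without explant replicate 3 and 2265 with DESeq2.

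At 12 h the sources differed in 2211 unigenes, 1099 higher and 1112 lower in explants. BMK_Unigene_105302 and BMK_Unigene_122841 stood at 20.6 ± 1.87 and 19.1 ± 2.06 CPM (SD, n = 3) in seedlings and at 0 reads in explants, at least 308-fold and at least 284-fold lower (adjusted p = 0.011 and 0.002). BMK_Unigene_132716 had 0 reads in seedlings and 74.6 ± 118 CPM in explants, from 3.56 to 211, the highest value being that of explant replicate 1 (adjusted p = 0.0028). BMK_Unigene_123783 had 412 reads in explants, 9.96 ± 7.78 CPM, and 1 read in seedlings (adjusted p = 0.0055).

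The count at 12 h moved with single libraries of both sources and with the libraries in the fit. It was 1073 without explant 12 h replicate 1, 3339 without explant replicate 2, 1349, 1402 and 1471 without seedling replicates 1, 2 and 3, and 334 in a fit of these 6 libraries alone. DESeq2 called 3378. Of the 2211, 49.7% were higher in explants, against 36.4% with limma on log2(FPKM + 1) without TMM scaling. The share was 57.9% with DESeq2 and 58.2% at a mean FPKM of at least 5, so the balance of directions at 12 h depended on the processing.

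At 24 h, 1905 unigenes differed, 838 higher and 1067 lower in explants. BMK_Unigene_106745 (6.76 ± 4.18 CPM) and BMK_Unigene_085061 (3.76 ± 1.17 CPM; SD, n = 3) had reads in seedlings and 0 in explants, at least 125-fold and at least 69.3-fold lower (adjusted p = 0.0018 and 0.0011); without seedling replicate 2 the first bound falls to 81.1-fold. BMK_Unigene_006255 had 5125 reads in explants (92.1 ± 19.1 CPM) and 1 in seedlings (adjusted p = 0.02), a call lost without any 1 of the 3 seedling libraries. BMK_Unigene_027917 had 94.6 ± 58.3 CPM in explants and 0 reads in seedlings (adjusted p = 0.046), a call lost without any 1 of the 6 libraries and with the replicate block (adjusted p = 0.051). The count was 1141 without explant replicate 2, 1118 without explant replicate 3 and 3065 with DESeq2. Of the 1905, 44% were higher in explants, against 59.7% with limma on log2(FPKM + 1) without TMM scaling. There the median unigene lay 0.11 higher in explants on the log2 scale.

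At 48 h the difference between sources covered 961 unigenes, 378 higher and 583 lower in explants. BMK_Unigene_106745 (13.6 ± 10.3 CPM) and BMK_Unigene_118172 (9.15 ± 8.6 CPM; SD, n = 3) were again present in seedlings and at 0 reads in explants, at least 207-fold and at least 139-fold lower (adjusted p = 0.0023 and 0.0041), or 118-fold and 63.6-fold without seedling replicate 2. BMK_Unigene_075083 had 8.43 ± 4.7 CPM in explants and 0 reads in seedlings, at least 161-fold higher (adjusted p = 0.0057). BMK_Unigene_010716 had 6.39 ± 8.15 CPM in explants and 0 reads in seedlings (adjusted p = 0.026), a call lost without any 1 of the 3 seedling libraries or explant replicate 2. Since the seedling libraries all held 0 reads, none of them carried the call by its own value. The count was 584, 605 and 400 without seedling replicates 1, 2 and 3, and 508, 385 and 537 without explant replicates 1, 2 and 3. It was 1629 with limma, 2083 with DESeq2 and 1772 from these 6 libraries alone. Of the 961, 39.3% were higher in explants, against 51.9% on quantile-normalized log2(FPKM + 1).

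A small set of unigenes separated the sources at all 4 times. There were 24 unigenes called higher in explants at 6, 12, 24 and 48 h and 52 called lower at all 4 times, where independent lists of the same sizes would share 0.0079 and 0.012. Lists from 1 fit are not independent, so these values are a yardstick and no test. Both sets were chosen by their difference in these same libraries, so their read shares must differ between the sources and only describe its size. The 24 took 0.116% ± 0.00961 (SD, n = 3) of the reads in explants at 6 h and 0.12% ± 0.00862 at 48 h, against 0.0298% ± 0.00186 and 0.0278% ± 0.00201 in seedlings. The 52 took 0.209% ± 0.06 in seedlings at 6 h and 0.207% ± 0.0319 at 48 h, against 0.0452% ± 0.0103 and 0.0634% ± 0.00382 in explants. Of the 2293 unigenes called higher in explants at any time, 1631 passed the threshold at 1 time alone, as did 1618 of the 2371 called lower. That does not show a difference limited to 1 time, since a lasting difference can miss the threshold. In the simulation, 49% of changes of 1.5 on the log2 scale were recovered at 6 h. DESeq2 gave 64 and 107 unigenes at all 4 times in place of 24 and 52.

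Where a unigene was called between sources at more than 1 time, its direction was mostly shared. Of the unigenes called at both times, 98.4% of 486 had 1 direction at 6 h and 12 h, 99.4% of 468 at 6 h and 24 h, 94.7% of 207 at 6 h and 48 h, 94% of 470 at 12 h and 24 h, and 98.8% of 485 at 24 h and 48 h. The exception was 12 h with 48 h, where 69.9% of 206 shared a direction. The share was 82.5% of 212 without explant 12 h replicate 1 and 82.4% of 108 without seedling 48 h replicate 3. These comparisons share no library. Across all tested unigenes, which are not independent replicates, the Pearson correlation of the source differences was 0.08 for 6 h with 12 h, 0.2 for 6 h with 24 h, 0.43 for 6 h with 48 h, 0.24 for 12 h with 24 h, 0.23 for 24 h with 48 h and -0.17 for 12 h with 48 h. Without the 3 libraries that stood apart the first 2 were both 0.04, 12 h with 24 h was 0.45 and 24 h with 48 h was 0.1; limma gave 0.44, 0.44, 0.39, 0.36 and 0.49 for the first 5. The value for 12 h with 48 h was -0.03 without seedling 48 h replicate 3 and 0.04 with limma, and its Spearman rho was -0.03.

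The second question was what changed in each source with time in the medium. In seedling stems, 294 unigenes had changed by 12 h, 1344 by 24 h and 3041 by 48 h, each against 6 h, with 210, 978 and 1939 of them higher. BMK_Unigene_007998 fell from 12.7 ± 3.63 CPM (SD, n = 3) at 6 h to 2.51 ± 0.618 at 12 h, 0.428 ± 0.238 at 24 h and 0 reads at 48 h, at least 242-fold lower (adjusted p = 5.4e-05 for 48 h against 6 h). BMK_Unigene_131924 fell from 4.54 ± 4.2 CPM to 0 reads (adjusted p = 0.025), a call lost with limma and without any 1 of 6 h replicate 3 and the 3 libraries at 48 h. BMK_Unigene_006255 rose from 0 reads at 6 h to 73.3 ± 11.4 CPM at 48 h, at least 1180-fold (adjusted p = 0.011), and BMK_Unigene_021862 from 0 reads to 34.3 ± 30.7 CPM, at least 552-fold (adjusted p = 0.0024), or 270-fold without 48 h replicate 3.

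Of the 3041 seedling unigenes at 48 h, 63.8% were higher, against 53.2% on quantile-normalized log2(FPKM + 1). The median tested unigene lay 0.13 higher at 48 h on the log2 scale, but 0.02 higher without 48 h replicate 3, the library with additional unigenes, and 0.04 lower after quantile normalization. Without that replicate 2557 unigenes were called. The 24 h count was 826 without 6 h replicate 3 and 2221 with DESeq2. The 12 h count of 294 was 147, 193 and 82 without 6 h replicates 1, 2 and 3, 87, 145 and 161 without 12 h replicates 1, 2 and 3, and 993 with DESeq2.

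In explant stems, 512 unigenes had changed by 12 h, 1916 by 24 h and 4437 by 48 h, with 277, 1273 and 2516 of them higher. BMK_Unigene_028148 rose from 0 reads at 6 h to 11 ± 8.71 CPM (SD, n = 3) at 48 h, at least 178-fold (adjusted p = 0.0011), or 96.9-fold without 48 h replicate 3. BMK_Unigene_010901 rose from 0 reads at 6 h to 1.89 ± 0.772 CPM at 24 h and 9.21 ± 3.26 at 48 h, at least 150-fold (adjusted p = 3e-05 for 48 h against 6 h). BMK_Unigene_124514 fell from 12.4 ± 5.64 CPM at 6 h to 1.78 ± 0.887 at 24 h and 0 reads at 48 h, at least 188-fold (adjusted p = 0.00015 for 48 h against 6 h). BMK_Unigene_122880 fell from 8.95 ± 1.59 CPM to 2.39 ± 0.895 and 0 reads, at least 136-fold (adjusted p = 0.00068). Seedling means moved the same way from 6 h to 48 h. BMK_Unigene_028148 went from 1.46 ± 0.648 to 5.22 ± 4.05 CPM and BMK_Unigene_010901 from 0.144 ± 0.125 to 4.15 ± 1.47. BMK_Unigene_124514 went from 9.37 ± 2.8 to 1.84 ± 1.76 CPM and BMK_Unigene_122880 from 2.16 ± 0.84 to 0.44 ± 0.762.

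The 512 explant calls at 12 h came from the fit of all 24 libraries, and a fit of these 6 alone called 2. The count was also 322 and 168 without 6 h replicates 2 and 3, 1247 without 12 h replicate 2 and 1213 with DESeq2, and the share higher was 54.1%, against 40% with limma and 66% with DESeq2. The 24 h count was 1051 without 24 h replicate 3. Of the 4437 at 48 h, 56.7% were higher, against 69.7% with limma on log2(FPKM + 1) without TMM scaling, where the median unigene lay 0.12 higher at 48 h.

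**Figure D4:**
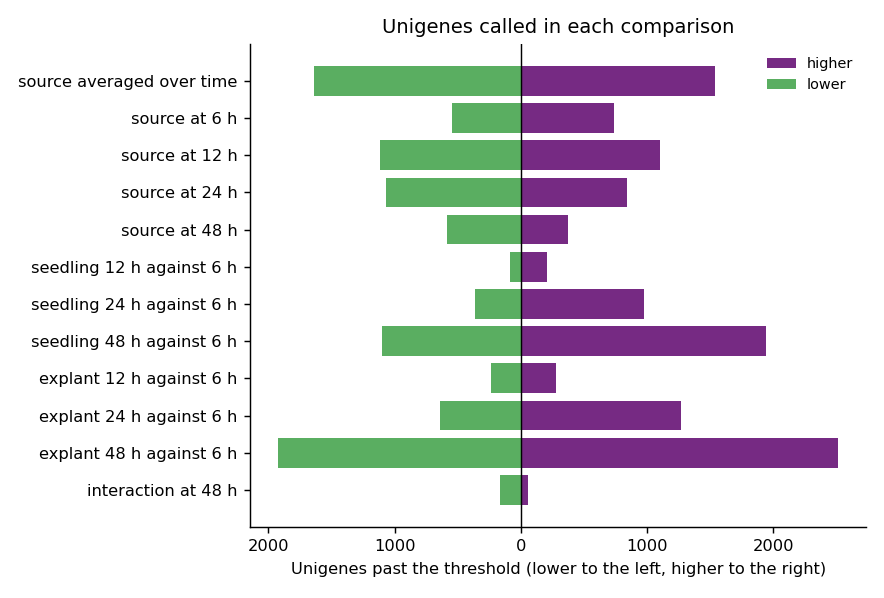
Bars give the number of unigenes past the threshold in each comparison, with those lower to the left of 0 and those higher to the right (x axis); source comparisons are explant minus seedling, and the interaction is the explant change minus the seedling change. The change from 6 h to 48 h is the longest bar for each source, with 3041 unigenes in seedlings and 4437 in explants.

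The third question was whether stems of the 2 sources changed alike. Between 6 h and 48 h, 1015 unigenes rose in both sources and 637 fell in both, against 153 and 66.3 for independent lists of these sizes, and 13 went in opposite directions (204 for independent lists). The direction was shared by 99.2% of the 1665 unigenes called in both, which come from separate libraries. Both lists come from 1 fit and share each unigene's dispersion, so the size of the overlap is no test of a shared change. The share with 1 direction does not rest on the values for independent lists. Over all tested unigenes, which are not independent replicates, the 2 changes correlated at a Pearson r of 0.34 (0.56 with limma) and a Spearman rho of 0.44. The 1015 rising unigenes took 1.69% ± 0.201 (SD, n = 3) of the reads in seedlings at 6 h, 3.12% ± 0.318 at 12 h, 4.41% ± 0.147 at 24 h and 6.22% ± 0.267 at 48 h. In explants they took 1.5% ± 0.186, 2.34% ± 0.693, 4.8% ± 0.694 and 6.66% ± 0.464 at the same times. The 637 falling unigenes went from 6.56% ± 0.355 to 2.29% ± 0.0842 of the reads in seedlings and from 6.86% ± 0.525 to 2.27% ± 0.171 in explants.

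**Figure D5:**
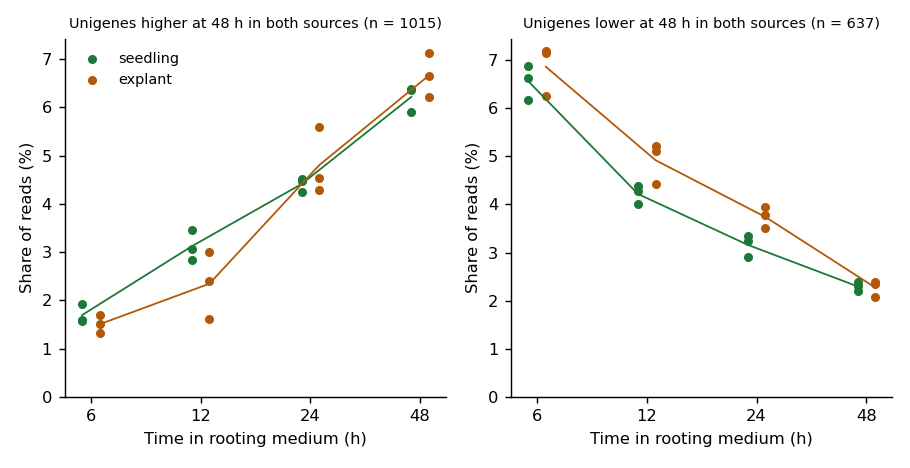
Share of each library's reads (y axes, percent) taken by the 1015 unigenes that rose (left) and the 637 that fell (right) from 6 h to 48 h in both sources, by time in rooting medium (x axes); points are libraries and lines join the means of 3. The unigenes were chosen by their change from 6 h to 48 h, in the fit of all 24 libraries. The rising set goes from 1.69% to 6.22% in seedlings and from 1.5% to 6.66% in explants.

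Whether the change itself differed between the sources was tested separately. The change from 6 h to 48 h differed by source for 224 unigenes, 60 with a higher and 164 with a lower change in explants. That count ranged from 72 to 220 when 1 library of the groups compared was left out. The F test of any difference in time course was passed by 1560 unigenes, a count that ranged from 592 to 3853 when 1 library was left out. BMK_Unigene_132716 (adjusted p = 0.028), BMK_Unigene_021862 (adjusted p = 0.037) and BMK_Unigene_010901 (adjusted p = 0.04) were among the 1560. BMK_Unigene_021862 was at 0 reads in seedlings and 34.7 ± 12.2 CPM (SD, n = 3) in explants at 6 h. At 12 h it was at 25.2 ± 38.6 CPM in seedlings (0.633 to 69.7) and 37.1 ± 35.2 in explants (9.83 to 76.8), so the sources overlapped. It was at 0.358 ± 0.62 and 68.5 ± 18.1 CPM at 24 h, and at 34.3 ± 30.7 and 122 ± 119 CPM at 48 h. Its change from 6 h to 48 h alone was not called as different (adjusted p = 0.13). Of the 224, 26.8% were higher, against 41.5% with limma and 45.3% on quantile-normalized log2(FPKM + 1), and DESeq2 called 1027.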

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

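All weighing of the 2 library patterns here was chosen after the patterns were seen; the test of unigene length was run on values not yet looked at.

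Stems of the 2 sources changed differently with time in some unigenes. The test of the difference itself found 224 unigenes for the change from 6 h to 48 h and 1560 over all times. The 224 became 117, 72 and 131 without seedling 6 h replicates 1, 2 and 3, 134 and 81 without seedling 48 h replicates 2 and 3, 138 without explant 6 h replicate 3, and 107, 115 and 96 without explant 48 h replicates 1, 2 and 3. The 1560 became 3853 without explant 12 h replicate 2, 1031 without seedling 6 h replicate 2, 592, 713 and 614 without seedling 12 h replicates 1, 2 and 3, and 638 without seedling 48 h replicate 3. It became 988 without explant 24 h replicate 2 and 936, 742 and 766 without explant 48 h replicates 1, 2 and 3. In 99 random exchanges of source within each time the highest counts were 2 and 3, so 1 of the 100 assignments, the real one, gave as many in each case; as an exchange mixes the sources within groups and so widens their spread, this does not decide whether chance gave the 224 and the 1560.

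Among the named unigenes, 3 had time courses that differed between sources in the same F test: BMK_Unigene_021862 (adjusted p = 0.037), BMK_Unigene_132716 (adjusted p = 0.028) and BMK_Unigene_010901 (adjusted p = 0.04). BMK_Unigene_132716 averaged 5.18 ± 4.63 CPM (SD, n = 3) in explants at 6 h, 74.6 ± 118 at 12 h and 0.187 ± 0.323 at 24 h, and its 12 h value rests on 1 library at 211 CPM.

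Untested unigenes carried a signal of their own in 3 libraries. Counting untested unigenes with at least 10 reads in a library and over 90% of their depth-scaled reads there, seedling 24 h replicate 3 had 5121, explant 48 h replicate 2 had 817 and seedling 48 h replicate 3 had 729. The other 21 libraries had at most 60.

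Seedling 24 h replicate 3 and seedling 48 h replicate 3 had more unigenes with a read than the other 22 libraries. Depth is argued against: thinned to 13774616 reads each, they kept 41149 and 40623 such unigenes, and the highest of the others had 32657. A response of seedling stems at 24 h is argued against too, since the other 2 libraries of that group had at most 29275, below the highest of the 18 libraries of other groups (32474); at 48 h the other 2 had 31369 and 32657, on both sides of that value, which leaves the question open. RNA of another organism or tissue may be the source: 5077 unigenes had at least 10 reads in seedling 24 h replicate 3 and 0 in the other 22, and 1727 of them had a read in seedling 48 h replicate 3, with a Spearman rho of 0.27 between the 2 libraries across these unigenes. Without unigene sequences this cannot be told apart from rare transcripts of the plant. Across 23766 unigenes, the log2 ratio of seedling 24 h replicate 3 to its group had a Spearman rho of -0.28 with relative unigene length. That was the largest in size of the 24 libraries, and seedling 48 h replicate 3 had -0.01. Whether the length trend bears on the additional unigenes was not tested.

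Explant 12 h replicate 1 correlated at 0.932 with the other libraries of its group, the lowest value of the 24 libraries. Seedling 24 h replicate 3 was close at 0.937, the other explant 12 h libraries stood at 0.944 and 0.95 and the other seedling 24 h libraries at 0.957 and 0.954, and the 18 libraries outside these groups at 0.962 or more. A few abundant unigenes are argued against, since the median unigene of 23766 deviated from the group by 0.52 on the log2 scale, against 0.41 and 0.34 in the other libraries of its group, up to 0.33 in seedling 24 h and at most 0.3 in the other 18. A wrong label within the series stays open: its highest mean correlation was 0.934, with explant 6 h and not with its own group, though the other 2 libraries of its group were also closest to explant 6 h (0.962 and 0.955). The value of 0.934 lies below those within explant 6 h (0.967 to 0.972), but a library that stands apart could lie as low in its true group. A loss of RNA that depends on transcript length is argued against. The Spearman rho of its log2 ratio to its group with relative unigene length was -0.01, inside the range of the other 23 libraries (-0.28 to 0.19). The extremes of that range were seedling 24 h replicates 3 (-0.28) and 1 (0.19). Outside that group the values ran from -0.14 (explant 24 h replicate 2) to 0.09 (explant 24 h replicate 1), and -0.01 lies inside these too. No biological explanation was tested, and the cause stays open.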

How the results depend on the processing

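Every comparison was recomputed under the alternatives fixed before the data were examined and under 3 chosen after seeing the data (limma as first designed, DESeq2, and a fit without the 3 libraries that stood apart). Of 140 counts, 111 stayed within 1.5 times of the main value, 20 rose above it and 9 fell below it. The cause was not tested except where fewer unigenes or libraries entered or the pseudocount was changed. The averaged source count of 3179 became 1516 with limma, 1510 without its trend and 1532 after quantile normalization, all on log2(FPKM + 1). With limma on log2(FPKM + 0.1) it was 3246, so the fall to 1516 went with the pseudocount and not with limma itself. At a mean FPKM of at least 5 the averaged source count was 1024. That filter also took explant 48 h against 6 h from 4437 to 2898. DESeq2 gave more calls: 2265, 3378, 3065 and 2083 for source at 6, 12, 24 and 48 h, 993 and 2221 for seedling 12 h and 24 h, 1213 for explant 12 h and 1027 for the interaction at 48 h. Source at 48 h became 1629 with limma, 1606 without its trend and 2008 after quantile normalization. No filter gave 515 for seedling 12 h, 545 for the interaction at 48 h and 2530 for the interaction F test, and quantile normalization 371 for the interaction at 48 h. Fits of only the groups compared gave 334 for source at 12 h, 1772 for source at 48 h, 840 for seedling 12 h, 2 for explant 12 h and 703 for the interaction at 48 h. Without the 3 libraries that stood apart, the counts were 1160 for source at 12 h, 671 for seedling 12 h, 398 for the interaction at 48 h and 896 for its F test.

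Leaving out 1 library at a time of the groups compared, and none of the others, gave 574 to 1094 for source at 6 h, 1073 to 3339 at 12 h, 1118 to 1572 at 24 h and 385 to 605 at 48 h. It gave 82 to 193 and 826 to 1204 for seedling 12 and 24 h, and 168 to 1247, 1051 to 1922 and 3540 to 4168 for explant 12, 24 and 48 h. Seedling 48 h stayed within 1.5 times of 3041, and the averaged source count stayed between 2933 and 3333, the interaction at 48 h between 72 and 220, and the F test between 592 and 3853. With fewer libraries in a group, calls can be lost whichever library is left out, so a lower count does not single out 1 library. Libraries outside a comparison also moved it: without explant 12 h replicate 1, the unigenes called between sources at both times rose from 207 to 342 for 6 h with 48 h and from 485 to 801 for 24 h with 48 h. Of the calls of single named unigenes, 381 recomputed values stayed past the threshold, 27 did not and 0 reversed. Named unigenes were picked by the largest change without overlap, most against a group with 0 reads. Such calls could hardly reverse, so the 0 is no added support.

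Replicate numbers are shared by all groups but did not pair the libraries: deviations of same-numbered libraries correlated between -0.24 and 0.34 and exceeded 0.1 in every pair for 0 of 10 contrasts, and 9 of 24 libraries correlated best with their own number. With the replicate block, counts stayed within 1.5 times: 3022 for the averaged source, 1139, 2081, 1720 and 889 at 6, 12, 24 and 48 h, 248, 1269 and 2984 for seedlings, 409, 1796 and 4319 for explants, 208 for the interaction at 48 h and 1076 for its F test. The F test was not run with DESeq2, and the alternatives meant for gene lists were not run because the table has no names. With 3 libraries a group, simulated changes of 1.5 on the log2 scale at 6 h were recovered in 49% of cases, so changes of that size were in part missed.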

Other observations

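The tests of the time-course difference below were chosen after the pattern was seen; the splits of the libraries were set out before their results were seen.

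Some unigenes had reads in 1 source alone. Among those called in the averaged comparison, 22 had 0 reads in all 12 explant libraries and 23 had 0 reads in all 12 seedling libraries. Most were not present throughout the other source: 2 of the 22 had a read in all 12 seedling libraries (BMK_Unigene_106745 and BMK_Unigene_112233, the latter named after its values were seen), and 0 of the 23 had a read in all 12 explant libraries.

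The source difference at 12 h ran against the later change of explant stems. Of the 809 unigenes called both between sources at 12 h and between 48 h and 6 h in explants, 733 went in opposite directions (154 for independent lists). Without explant 12 h replicate 1 it was 383 of 453. These comparisons share no library but come from 1 fit. At 24 h the opposite unigenes were 192 of 446.

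A hypothesis from this is that explant stems may go through the shared change more slowly. The mean signed log2 level of the 1652 unigenes that rose or fell in both sources was scaled to 0% at 6 h and 100% at 48 h of each source. Seedling libraries stood at 45.6% ± 5.49 (SD, n = 3) at 12 h and 71.5% ± 2.37 at 24 h, and explant libraries at 24.7% ± 12.8 and 68.8% ± 9.01. The difference was -20.9 percentage points at 12 h, where the same libraries prompted the hypothesis. At 24 h, the separate test, it was -2.79 (two-sided exact permutation p = 0.7 over 20 arrangements, where the smallest possible is 0.1), so a slower course stays open. The average over both times was -11.8. Without explant 12 h replicate 1, itself at 10.3%, the difference was -13.6 at 12 h. The average was then -8.2 (two-sided exact permutation p = 0.09 over 200 arrangements). Explant 12 h replicates 2 and 3 stood at 29.4% and 34.6%, below the seedling 12 h range of 39.9% to 50.8%. A difference of the same sign thus remained at 12 h without that library, which had enlarged it. Whether the remainder arose by chance is not decided, so that library as the sole cause is not excluded. The 1652 come from the fit of all 24 libraries; with 1835 unigenes called in a fit of the 6 h and 48 h libraries alone, the average was -12.8, and -8.41 without that library. Scaling is argued against: with rising and falling unigenes weighted equally, so that a scaling factor cancels, the average was -11.5. It was -11.7 with median-ratio factors and -11.5 on FPKM, which is scaled to library size but not by TMM.

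BMK_Unigene_033917, chosen after its values were seen, took 8.36% of the reads of seedling 24 h replicate 2 and 0.485% to 1.77% in the other 23 libraries. BMK_Unigene_106745 and BMK_Unigene_118172 were highest in replicate 2 at all 4 seedling times. Across 23766 unigenes with a mean of at least 1 CPM, 1 replicate number was highest at all 4 times in 3.82% in seedlings and 4% in explants, where chance gives 3.7%.

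Other splits of the libraries gave few calls. For the averaged source comparison, 1 of 100 assignments, the real one with 3179 unigenes, gave as many. The highest of the 99 random exchanges of source within each time gave 0. This argues against an absence of any source difference, provided the libraries are independent, which the labels do not state. It does not show how many of the 3179 arose by chance, since an exchange mixes the sources within groups and widens their spread. For each comparison of 3 libraries with 3, 1 of the 10 splits, the real one, gave as many; 10 splits are too few for a share under 0.05. The highest of the other 9 was 0 for source at 6 h (real 1277), 1 at 12 h (2211), 1 at 24 h (1905) and 0 at 48 h (961). It was 0 for seedling 12, 24 and 48 h (294, 1344 and 3041), 32 for explant 12 h (512), and 0 for explant 24 h and 48 h (1916 and 4437).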
